A study of Mus musculus with 12 samples.

How the data were processed

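Polyadenylated RNA of R1/E mouse embryonic stem cells, taken up in TRIzol per the labels, was sequenced in 12 libraries as paired-end reads on an Illumina NovaSeq instrument. The counts per gene were made by the authors, whose processing notes name fastp, STAR and the genome build mm10 without versions, and they were deposited as raw whole numbers with no normalization. In each library the deposited matrix held the same values as the column of that library's own counts that ignores strand. The strand-specific columns held about equal shares (50.01% to 50.38% in the first of them), so the counts without regard to strand were used. All 12 count columns of the matrix were used and 0 were left out; the STAR tallies of unmapped, multimapping, ambiguous and no-feature reads served as quality measures. Gene identifiers were matched to the GENCODE annotation of GRCm38. Of 55401 identifiers, 54349 matched exactly, 792 matched without the version suffix and 260, with 0.013% of the counts, had no symbol. Genes without a symbol were tested and counted in totals and not named.

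Libraries were grouped by their labels into siControl (2), siTop2a (4), shControl (2) and shTrim28 (4). The siTop2a labels name the reagent si2 for replicate 1 and si12 for replicates 2 to 4, and their meaning is not stated. Genes were kept by edgeR's filterByExpr with the groups, which left 19756, and libraries were scaled by TMM factors. A gene expressed in a single group passes this filter, so genes silent elsewhere enter only through the group where they are high. A single model with 4 group means over the 12 libraries was fitted by edgeR 4.0.16 (robust quasi-likelihood) in R 4.3.3, so that the groups shared an estimate of the spread. The contrasts were siTop2a minus siControl, shTrim28 minus shControl, the former minus the latter, and shControl minus siControl. Two-sided p-values from edgeR's quasi-likelihood test were adjusted by the Benjamini-Hochberg method over the genes tested, and genes with an adjusted p under 0.05 were called. The SE of a log2 fold change was taken as its absolute value divided by the square root of F. An exact permutation test of 4 libraries against 2 has 15 splits and a smallest p of 0.067, so no single gene was tested that way. CPM were normalised by the TMM factors. A fold against a group with 0 counts was computed against a floor of 3 counts over the group, and with 1 to 3 counts the CPM ratio was given with its exact 95% interval for the counts. Library depths and these intervals cover counting error only. On simulated counts with 18963 genes, edgeR recovered 46% and 44% of genes changed by 1 on the log2 scale and 90% and 90% of those changed by 2 in the designs of the siTop2a and the shTrim28 comparison. For the difference of the effects it recovered 9% and 76%. False calls made up 3.5%, 2.2% and 4.5% of the simulated calls. These counts were drawn independently per gene and library, with 100 genes changed by 1 and 100 by 2. They held no number series, pairs of replicates or chromosome shifts, and a far smaller share of changed genes than the 8055 of 19756 called in shTrim28. They therefore give neither the rate of false calls nor the recovery in the real data.

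Before the data were examined, 22 gene lists with 638 entries, the tests, the alternatives and the rule for named genes were fixed. The rule named Top2a, Trim28, Top2b, Pou5f1, Sox2, Nanog, Ezh2, Suz12, Eed and Setdb1. For each knockdown it named the 10 genes that rose and the 10 that fell most among those called, with a mean CPM of at least 1 over the comparison and every knockdown library beyond every control library. It named up to 4 members per list with the smallest adjusted p, or 2 where none passed, the 5 highest and the 5 lowest genes of the difference, and 5 genes per direction among those called in both knockdowns. Gene models, names ending in Rik and entries without a symbol were left out of the top genes, so that 0 and 1 better-ranked genes were passed over in siTop2a (rises and falls) and 4 and 3 in shTrim28. Members of a list may be gene models. Lists were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, with an estimated correlation beside it, and with fry, which tests whether a list's genes move one way on balance. These tests ran on log2 CPM with a prior count of 2 in place of the count object named in the fixed design, on which camera gave z-scores that were not finite. Their p-values were adjusted over the 22 lists of a contrast. With an estimated correlation 0 of the 22 lists were called in either knockdown, with the lowest adjusted p = 0.675 in siTop2a and 0.218 in shTrim28, while fry called 2 and 19. Overlaps were tested with the one-sided Fisher's exact test over the genes tested.

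The alternatives were size factors of the DESeq2 kind or library size alone, DESeq2 1.42.0, no filter or a CPM of at least 1 in at least 4 libraries, a single strand column, an adjusted p under 0.01, a log2 change of at least 1, the replicate number as a block, the number series as a term, subsets by hairpin or number series, and each library left out in turn. In the counts of changed genes the number series entered as 1 term common to the siRNA and shRNA libraries, and between hairpins as a term of the shRNA libraries. The group means of a subset with a lone control library were tested with the spread of the other groups. Tables were prepared with Python 3.11.15 and pandas 2.3.3 and figures drawn with matplotlib 3.10.9.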

Results

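Gene expression was measured by RNA sequencing in R1/E cells, a line of mouse embryonic stem cells, in 12 libraries of polyadenylated RNA. The series asked how loss of Top2a or of Trim28 alters transcription in these cells, and how both relate to Polycomb repressive complex 2 (PRC2), which deposits the repressive mark on histone H3 lysine 27. Top2a encodes DNA topoisomerase II alpha, which untangles DNA during replication and chromosome segregation. Trim28 (KAP1) is a corepressor that KRAB zinc finger proteins bring to retroelements and imprinted regions. Top2a was knocked down with short interfering RNA (siTop2a, n = 4, against siControl, n = 2) and Trim28 with short hairpin RNA (shTrim28, n = 4, against shControl, n = 2). The shTrim28 libraries came from hairpin sh1 in replicates 1 and 3 and from hairpin sh4 in replicates 2 and 4. The labels give the libraries numbers from 1 to 9 and from 64 to 80, with gaps, and do not say what the numbers mean. They were grouped here into a first and a second number series. The second joins shRNA libraries 64 to 66 with siTop2a libraries 79 and 80. The second series held siTop2a replicates 3 and 4, shControl replicate 2 and shTrim28 replicates 3 and 4, and no siControl library. The series and the Top2a knockdown cannot be told apart for siTop2a replicates 3 and 4.

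The reads assigned to genes numbered 22470453 to 37557625 per library. They were 25085423 and 23481429 in siControl, 22470453, 28155094, 30153073 and 29362009 in siTop2a, 28103514 and 37557625 in shControl, and 27093221, 23144793, 33673623 and 29430581 in shTrim28. The share of reads that fell in no annotated exon was 7.24% and 6.23% in siControl, 4.76% and 4.73% in siTop2a replicates 1 and 2, and 9.16% and 12.3% in siTop2a replicates 3 and 4. It was 7.31% and 7.04% in shControl and 6.34% to 7.25% in shTrim28. No pair of replicates agreed within sampling noise: the chi-square per degree of freedom over genes was 4.62 for siTop2a replicates 1 and 2 and 9.45 to 95.5 for the other pairs. The first principal component, with 64.6% of the variance, separated the 4 shTrim28 libraries (scores of 81.9 to 138) from the other 8 (scores of -82.4 to -26.6). The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples. That spread may be technical. Levels are given as normalised CPM, the counts of a gene scaled by library size, as mean ± SD, with n = 2 in control groups and n = 4 in knockdown groups. Changes are log2 fold changes ± SE, with Benjamini-Hochberg adjusted p from edgeR's quasi-likelihood test over 19756 genes. Coordinates are those of GRCm38 (mm10). Counting did not use strand, so reads of overlapping and antisense genes cannot be told apart, and values of multi-copy families are uncertain because near-identical copies share reads.

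Each target gene was lower in every library of its own knockdown than in every control library. Top2a (ENSMUSG00000020914.17, chromosome 11, 98992943 to 99024189) measured 948 ± 16.4 CPM in siControl and 304 ± 38.5 CPM in siTop2a. Its level was 960 and 936 CPM in the siControl libraries and 283, 261, 334 and 340 CPM in siTop2a replicates 1 to 4. The change was -1.64 ± 0.15 (adjusted p = 0.000392), a 3.11-fold loss. Trim28 (chromosome 7, 12999114 to 13031035) measured 2291 ± 554 CPM in shControl and 306 ± 162 CPM in shTrim28, with 1899 and 2683 CPM in the control libraries and 146, 335, 224 and 518 CPM in the knockdown libraries. The change was -2.91 ± 0.35 (adjusted p = 2.73e-05), a 7.50-fold loss. Trim28 RNA did not pass the test in siTop2a (0.21 ± 0.36, adjusted p = 0.781). Top2a RNA fell in shTrim28, by 0.59 ± 0.15 on the log2 scale (adjusted p = 0.00608), from 905 ± 116 to 602 ± 60.6 CPM, and without shControl replicate 1 that call was lost (Top2a in Trim28 knockdown, -0.44, adjusted p = 0.113).

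**Figure D1:**
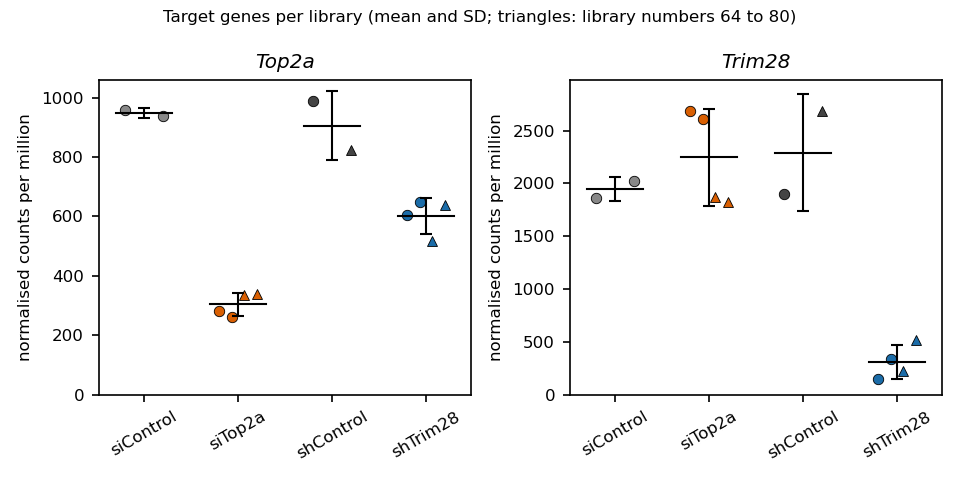
Normalised CPM of Top2a (left) and Trim28 (right) in each of the 12 libraries, with the mean and SD of each group as a line and bars. Triangles mark the second number series; siTop2a libraries lie between 261 and 340 CPM for Top2a, and shTrim28 libraries between 146 and 518 CPM for Trim28, all below their controls.

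Among the gene lists, 2-cell stage and hypoxia and glycolysis had the lowest camera adjusted p in siTop2a, with 15 of 30 members up and 5 of 30 down. Both lists moved the same way between the controls: the medians of shControl minus siControl were 0.995 and -0.42. Of 30 members tested of the 2-cell stage list, transcripts of the burst of zygotic transcription, 15 rose and 0 fell, with a median change of 1.77 in siTop2a. Among them, Usp17lc of the Usp17l deubiquitinase family went from 1.30 ± 0.0247 to 5.26 ± 0.898 CPM (2.01 ± 0.34, adjusted p = 0.011) and Tmem92 from 3.17 ± 0.319 to 10.3 ± 1.64 CPM (1.70 ± 0.33, adjusted p = 0.0169). The zinc finger gene Zfp352 rose by 2.79 ± 0.60 (adjusted p = 0.0241) and Gm21761 by 2.09 ± 0.45 (adjusted p = 0.0241). Of 30 members of the hypoxia and glycolysis list, 0 rose and 5 fell, with a median of -0.53. They included P4ha1, a collagen prolyl hydroxylase subunit (-0.99 ± 0.15, adjusted p = 0.00704), the angiogenic factor Vegfa (-1.37 ± 0.24, adjusted p = 0.011), hexokinase Hk1 (-1.02 ± 0.21, adjusted p = 0.0201) and phosphoglycerate kinase Pgk1 (-0.65 ± 0.16, adjusted p = 0.0379). Adjusted over the list alone, 28 members of the 2-cell stage list rose and 10 of the hypoxia and glycolysis list fell. In limma's camera test, with a preset correlation between genes of 0.01, the 2-cell stage list ranked above other genes (adjusted p = 4.60e-17; adjusted p = 0.675 with an estimated correlation) and the hypoxia and glycolysis list below (adjusted p = 4.81e-07; adjusted p = 0.725 with an estimated correlation). With the siRNA libraries numbered 4 to 9 only, siTop2a replicates 1 and 2, and the spread shared with the shRNA groups, 0 members of the 2-cell stage list passed (median 1.22) and 1 of the hypoxia and glycolysis list fell. Fitted alone, the same 4 libraries gave 23 rises in the 2-cell stage list (median 1.21), and 1 rise and 16 falls in the hypoxia and glycolysis list. With siTop2a replicates 3 and 4 only, whose reads held the larger share outside exons, 26 of the 2-cell stage list rose (median 2.24). Without either siControl library 0 members of both lists passed. Usp17l, Gm21761 and other members are multi-copy genes with uncertain counts.

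In all, 834 of the 19756 genes tested changed in siTop2a, 461 up and 373 down, and 4272 had an unadjusted p under 0.05. By the rule for named genes, which asks that every knockdown library lie beyond both control libraries, the largest rises included Gabra1, a GABA receptor subunit, with 195 counts over the siTop2a libraries against 3 in siControl (CPM ratio 28.1, 95% counting interval 9.47 to 137). Wnt8a, a ligand of the primitive streak, went from 0.222 ± 0.0725 to 3.83 ± 1.22 CPM (4.07 ± 0.44, adjusted p = 0.00117). The interferon-inducible GTPase genes Irgm1 (3.39 ± 0.50, adjusted p = 0.00585), Gbp2b (3.03 ± 0.56) and Gbp2 (2.83 ± 0.54) rose, as did Thbs1, which encodes thrombospondin 1 (3.01 ± 0.68), and the semaphorin gene Sema6a (3.33 ± 0.77). Kdm5d, a Y-linked histone demethylase gene, went from 0.243 ± 0.0423 to 3.71 ± 3.26 CPM (adjusted p = 0.0316), mostly in replicates 3 and 4 (5.78 and 7.18 CPM, against 0.594 and 1.3 in replicates 1 and 2). Fgfbp1 rose by 2.94 ± 0.68 and Grm6, a glutamate receptor gene, by 2.94 ± 0.53. The largest falls were those of Vstm2l (-2.81 ± 0.57, adjusted p = 0.02), the kainate receptor subunit Grik4 (-2.73 ± 0.39, adjusted p = 0.00455), the netrin receptor Unc5a (13.7 ± 1.61 to 2.35 ± 1.11 CPM, adjusted p = 0.00365) and the NMDA receptor subunit Grin2c (-2.52 ± 0.44). They were followed by the calcium pump Atp2b2 (-2.47 ± 0.40), complexin Cplx1 (-2.45 ± 0.37), histidine ammonia-lyase Hal (-2.43 ± 0.47), Camk2n1 (-2.37 ± 0.42), the histamine receptor Hrh3 (-2.34 ± 0.38) and neurexophilin Nxph4 (-2.31 ± 0.47). Replicates 3 and 4 lay farther from siControl than replicates 1 and 2 for Kdm5d (by 2.75 ± 0.39, adjusted p = 0.00215), Sema6a, Vstm2l, Unc5a and Nxph4. Kdm5d in Top2a knockdown lost its call without siTop2a replicate 3 or 4 (adjusted p = 0.0741 and 0.0546). The number of genes changed by Top2a knockdown was 175 within the first number series, but 7049 with the 4 siRNA libraries of that series fitted alone. With the series as a term common to siRNA and shRNA libraries it was 309. It was 2353 with siTop2a replicates 3 and 4 only, 1841 without a filter on low counts and 1395 with the 6 siRNA libraries only. With the replicate number as a block it was 2045, from replicates 1 and 2 alone, since no siControl library shares the number of replicates 3 and 4. It was 11 without siControl replicate 1, 3 without siControl replicate 2, 233 without siTop2a replicate 3, 492 without siTop2a replicate 4 and 1285 without shTrim28 replicate 4; DESeq2 called 1968.

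A minority of epiblast, primitive streak and pluripotency genes passed the test in siTop2a. Of 21 members of the formative and primed epiblast list, 4 rose and 0 fell: the transcription factor gene Pou3f1 (13.2 ± 0.632 to 33.7 ± 8.33 CPM, 1.35 ± 0.25, adjusted p = 0.0136), N-cadherin Cdh2 (1.5 ± 0.35), the growth factor Fgf5 (2.66 ± 0.65) and the Nodal antagonist Lefty2 (1.37 ± 0.34). Adjusted over the list alone, 11 rose and 1 fell. Camera gave this list an adjusted p of 7.72e-05, and adjusted p = 0.675 with an estimated correlation. Of 25 members of the mesoderm and primitive streak list, 6 rose (8 adjusted over the list alone), among them Wnt8a, the VEGF receptor Kdr (2.71 ± 0.49, adjusted p = 0.0135), Tbx20 (2.39 ± 0.45) and Wnt3 (2.18 ± 0.48). Its camera adjusted p was 0.00448, and adjusted p = 0.731 with an estimated correlation. Of 25 members of the naive pluripotency list, 0 rose and 2 fell (5 adjusted over the list alone), the transcription factors Klf4 (443 ± 47.4 to 187 ± 56.4 CPM, -1.25 ± 0.21, adjusted p = 0.0105) and Tbx3 (-1.39 ± 0.33, adjusted p = 0.0327). Pou5f1 (-0.29 ± 0.24), Sox2 (-0.60 ± 0.26) and Nanog (-0.61 ± 0.25), the core pluripotency factors, had adjusted p of 0.511, 0.194 and 0.166. The naive pluripotency list as a whole was not called (camera adjusted p = 0.135). With the siRNA libraries numbered 4 to 9 only, 2 members of the formative and primed epiblast list and 3 of the mesoderm and primitive streak list rose and 1 of the naive pluripotency list fell. Fitted alone, these 4 libraries gave 18 rises and 2 falls in the formative and primed epiblast list, 13 rises in the mesoderm and primitive streak list, and 7 rises and 13 falls in the naive pluripotency list. Without siControl replicate 1, 1 member of the mesoderm and primitive streak list and none of the other lists passed, and without siControl replicate 2 none of the 3 lists had a call.

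The cholesterol synthesis and imprinted lists were also called by camera in siTop2a, with few members past the test. In the cholesterol synthesis list, 0 of 23 members rose and 3 fell (5 adjusted over the list alone): the sterol oxidase Msmo1 (-0.95 ± 0.17, adjusted p = 0.011), the transcription factor Srebf2 (-0.80 ± 0.17, adjusted p = 0.0231) and Insig1, which retains SREBP in the endoplasmic reticulum (-0.63 ± 0.15, adjusted p = 0.0341). Camera gave the list an adjusted p of 0.00229, and adjusted p = 0.731 with an estimated correlation. Of 47 imprinted genes, 4 rose and 1 fell (15 and 2 adjusted over the list alone). The paternally expressed Mest (43.0 ± 4.58 to 102 ± 6.25 CPM, 1.25 ± 0.26, adjusted p = 0.0216), Peg10 (232 ± 4.45 to 835 ± 106 CPM, 1.85 ± 0.39, adjusted p = 0.0232) and Impact (0.92 ± 0.23) were among them, with Calcr (2.93 ± 0.68). The imprinted list had a camera adjusted p of 0.0286, and adjusted p = 0.731 with an estimated correlation. With the siRNA libraries numbered 4 to 9 only, or without either siControl library, 0 members of the cholesterol synthesis and imprinted lists passed. Fitted alone, the 4 libraries numbered 4 to 9 gave 3 rises and 11 falls in the cholesterol synthesis list and 19 rises and 7 falls in the imprinted list.

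The remaining lists were not called by camera in siTop2a. Of 13 PRC2 subunits, 0 rose and 0 fell by edgeR (1 rose adjusted over the list alone, 1 rose by DESeq2, 4 members had an unadjusted p under 0.05). Ezh2, the methyltransferase, changed by -0.39 ± 0.14 (adjusted p = 0.128), Suz12 by 0.34 ± 0.16, Eed by 0.05 ± 0.18 and the cofactor Lcor by 0.57 ± 0.16 (adjusted p = 0.062). Of 25 members of the Trim28 repressor complex list, 2 rose (2 adjusted over the list alone), the KRAB zinc finger gene Zfp809 (0.71 ± 0.17) and Morc2a (0.50 ± 0.13). Setdb1, the H3K9 methyltransferase, changed by 0.36 ± 0.14 (adjusted p = 0.145). Of 6 topoisomerases Top2a alone fell (2 others rose adjusted over the list alone), and Top2b changed by -0.51 ± 0.25 (adjusted p = 0.256). Among 28 interferon response genes 4 rose and 1 fell (7 and 1 adjusted over the list alone). Oasl2 (2.36 ± 0.48), the RNA sensor Ddx58 (1.43 ± 0.31) and Isg15, with 0 counts in siControl and a level at least 8.07-fold higher, rose, and Oas3 fell (-1.07 ± 0.25). Of 30 p53 targets, Plk3 (0.85 ± 0.17), Zfp365 (0.78 ± 0.17) and Perp (1.03 ± 0.27) rose and 0 fell (4 rose adjusted over the list alone). Of 22 neuroectoderm genes, Nes (1.54 ± 0.31), Gbx2 (1.68 ± 0.38) and Meis1 (1.64 ± 0.43) rose (4 rose and 2 fell adjusted over the list alone). Of 22 trophectoderm genes, Hand1 (2.46 ± 0.57) and the simple-epithelium keratins Krt8 (1.74 ± 0.41) and Krt18 (1.35 ± 0.35) rose and Gata2 fell (-1.31 ± 0.33), with 5 up and 1 down adjusted over the list alone and a median of -0.004 against a mean of 0.528. Of 49 bivalent developmental regulators, 4 rose, with Wt1 (2.57 ± 0.36), Tbx20 and Six1 (1.52 ± 0.29) among them, and the Wnt antagonist Sfrp1 fell (-1.74 ± 0.27), against 6 and 2 adjusted over the list alone.

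Of 38 germline genes in siTop2a, Dppa2 rose (1.08 ± 0.22), and Mael (-1.54 ± 0.24) and Mov10l1 (-1.17 ± 0.31), both of the piRNA pathway, fell with Rpl39l (-0.96 ± 0.22); adjusted over the list alone, 2 rose and 4 fell. Of 28 genes of the Hox clusters, Hoxc4 (-2.16 ± 0.52) and Hoxc13 (-1.35 ± 0.33) fell (1 up and 4 down adjusted over the list alone), and the median of the members (-0.24) and their mean (0.21) differed in sign. In the primitive endoderm and endoderm list, with 23 members, the chemokine receptor Cxcr4 fell (-1.39 ± 0.32), and adjusted over the list alone 2 rose and 1 fell. Among 23 fibroblast feeder cells markers, Thbs2 rose (3.43 ± 0.84) and Pdgfrb fell (-1.15 ± 0.27), with 4 up and 3 down adjusted over the list alone. Their median was 0.74, and 0.12 with the 5 members at 0 counts in siControl set to their lower bound; for the interferon response list these were 0.28 and 0.16. Cell cycle and stress genes gave few calls. Of 30 DNA replication genes the helicase subunit Mcm6 fell (-0.54 ± 0.14; 0 adjusted over the list alone). None of 32 genes of G2 and mitosis passed in edgeR (0 adjusted over the list alone, 2 fell by DESeq2, 2 members had an unadjusted p under 0.05), where the lowest p were those of the condensin gene Ncapd2 (-0.58 ± 0.17, adjusted p = 0.0683) and Kif23 (-0.38 ± 0.13). None of 24 genes of the integrated stress response passed either (0 adjusted over the list alone, 1 fell by DESeq2, 10 members had an unadjusted p under 0.05), with Asns at -0.81 ± 0.23 (adjusted p = 0.0625) and Nupr1 at -0.98 ± 0.34. Over the 16 lists not called, naive pluripotency included, the camera adjusted p ran from 0.0706 to 0.577. With the siRNA libraries numbered 4 to 9 only, 2 bivalent developmental regulators, 2 p53 targets and 1 trophectoderm gene rose and Top2a fell, and the other lists named here had no call. Fitted alone, these 4 libraries gave calls in every list named here, with 4 rises and 20 falls in the germline list and 5 and 17 in the G2 and mitosis list. Without either siControl library Top2a was the only call in these lists.

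Most members of the naive pluripotency list fell in shTrim28, and most fibroblast feeder cells markers rose. Of 25 members of the naive pluripotency list, 0 rose and 21 fell, with a median of -1.99. Klf4 went from 489 ± 4.10 to 116 ± 8.58 CPM (-2.08 ± 0.21, adjusted p = 7.53e-06), Tbx3 from 349 ± 55.3 to 41.5 ± 17.2 CPM (-3.07 ± 0.33) and Tfcp2l1 from 861 ± 289 to 132 ± 63.2 CPM (-2.71 ± 0.33). Among the core factors Pou5f1 (chromosome 17, 35506018 to 35510772) fell by 1.34 ± 0.24 on the log2 scale (adjusted p = 0.000508), Sox2 by 2.20 ± 0.26 (adjusted p = 2.17e-05) and Nanog by 1.99 ± 0.24 (adjusted p = 3.16e-05). Of 23 markers of fibroblast feeder cells, 22 rose and 0 fell, with a median of 5.63 and of 3.80 with the 2 members at 0 counts in shControl set to their lower bound. The collagen chains Col1a1 (chromosome 11, 94936224 to 94953042; 3.4 ± 0.426 to 352 ± 110 CPM, 6.70 ± 0.37, adjusted p = 3.08e-07), Col5a1 (24.96 ± 1.01 to 322 ± 83.2 CPM), Col5a2 (0.745 ± 0.128 to 267 ± 145 CPM) and Col1a2 (0.542 ± 0.364 to 161 ± 92.3 CPM) led them. Adjusted over the list alone, 22 naive pluripotency genes fell, and 22 fibroblast feeder cells markers rose and 1 fell. The camera adjusted p was 9.33e-09 for the naive pluripotency list (adjusted p = 0.288 with an estimated correlation) and 5.34e-12 for the fibroblast feeder cells list (adjusted p = 0.218 with an estimated correlation). Within the first and the second number series, 21 and 17 members of the naive pluripotency list fell and 20 and 19 of the fibroblast feeder cells list rose. With sh1 alone and sh4 alone, 22 and 18 of the naive pluripotency list fell and 21 and 19 of the fibroblast feeder cells list rose.

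**Figure D2:**
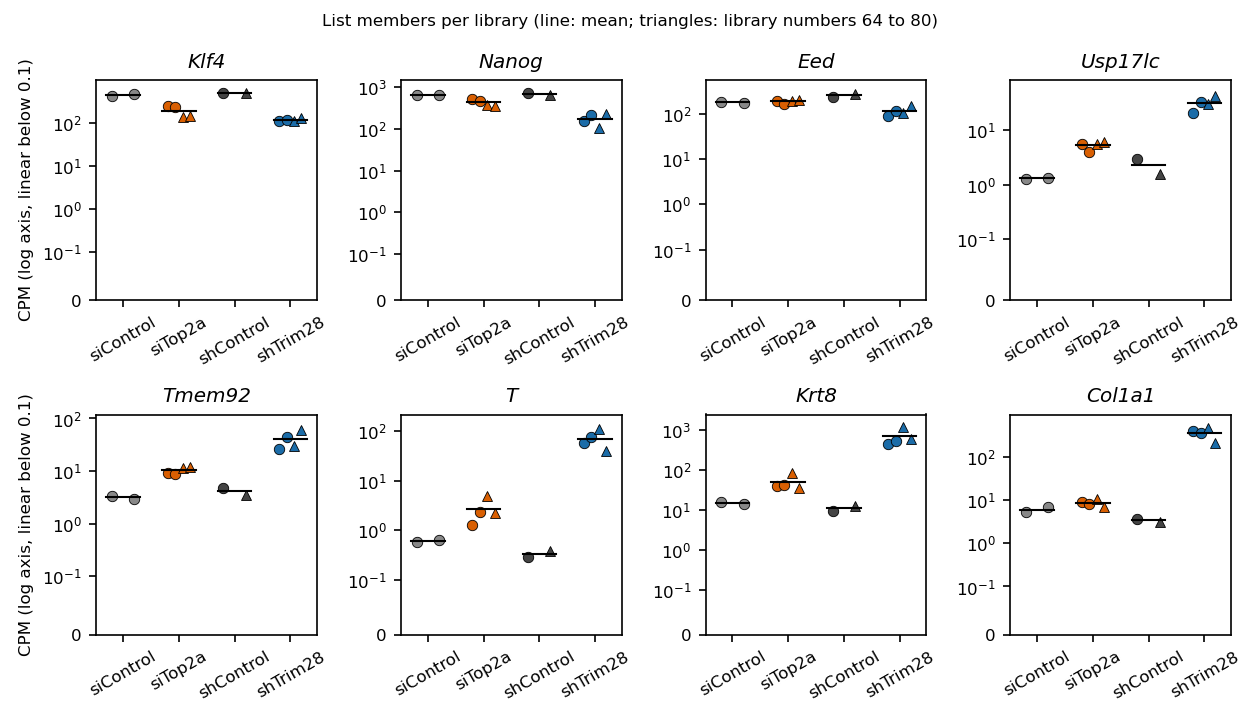
Normalised CPM, on a log axis that is linear below 0.1, of 8 named genes in each library, with the group mean as a line and triangles for the second number series. Klf4, Nanog and Eed lie lower in all 4 shTrim28 libraries than in the shControl libraries, and Usp17lc, Tmem92, T, Krt8 and Col1a1 higher.

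In all, 8055 of the 19756 genes tested changed in shTrim28, 4585 up and 3470 down, with changes of at least 1 on the log2 scale in 3406 and 1882 of them. By the rule for named genes, the largest rises included 6 genes with 0 counts in shControl. They were Hapln1, which links hyaluronan to proteoglycans (11.7 ± 12.3 CPM, at least 242-fold higher), the protease genes Pappa (11.1 ± 7.02 CPM, at least 236-fold) and Mmp12 (4.08 ± 2.03 CPM, at least 86.2-fold), Ctla2a (at least 78.4-fold), Ly6c1 (at least 77.3-fold) and the choline transporter Slc5a7 (at least 68.0-fold), the floor being 3 counts over the group. Smooth muscle actin Acta2 went from 0.197 ± 0.124 to 396 ± 243 CPM (10.88 ± 0.99, adjusted p = 4.30e-06) and the macrophage growth factor Csf1 from 0.168 ± 0.0839 to 138 ± 62.5 CPM (9.59 ± 0.64, adjusted p = 8.33e-07). The axon guidance receptor Robo2 had 2804 counts against 1 (CPM ratio 1570, 95% counting interval 282 to 62000), and the chemokine Cxcl11 3176 against 2 (CPM ratio 889, interval 246 to 7350). The largest falls were those of Catip (10.03 ± 2.23 to 0.430 ± 0.235 CPM, -4.56 ± 0.40), Piwil4 of the piRNA pathway (-4.19 ± 0.50), Hal (-4.15 ± 0.50), the inhibin subunit Inhbb (-4.07 ± 0.50) and the metal transporter Slc11a1 (-4.04 ± 0.35). Ndufa4l2 (-3.99 ± 0.52), Stra8, a gene of meiotic entry (-3.93 ± 0.61), Napsa (-3.90 ± 0.48), Igsf21 (-3.84 ± 0.47) and Lrriq4 (-3.83 ± 0.31) followed. Counting intervals and floors cover counting error only. Between hairpins, with the series as a term, Hapln1 (-2.54 ± 0.25, adjusted p = 3.28e-05), Robo2, Ctla2a, Pappa, Acta2, Mmp12, Csf1 and Cxcl11 were lower with sh4 than with sh1. Stra8 (2.31 ± 0.32, adjusted p = 0.000405), Piwil4, Inhbb, Slc11a1, Ndufa4l2 and Lrriq4 were higher with sh4. Without that term Csf1 and Inhbb alone of these passed. The number of genes changed by Trim28 knockdown was 5403 within the first number series and 3982 within the second, each with 1 control library, and ranged from 5408 to 8630 with 1 library left out.

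Most members tested of the mesoderm, neuroectoderm, endoderm and trophectoderm lists rose in shTrim28. Of 25 members of the mesoderm and primitive streak list, 17 rose and 0 fell (18 rose adjusted over the list alone), among them T (brachyury; 0.330 ± 0.0561 to 70.3 ± 28.9 CPM, 7.70 ± 0.64, adjusted p = 2.49e-06), Wnt3 (6.46 ± 0.54), Tbx20 (4.16 ± 0.40) and the Wnt target Sp5 (5.37 ± 0.53). Of 22 neuroectoderm genes, 13 rose and 0 fell (13 adjusted over the list alone), with the intermediate filament gene Nes (4.16 ± 0.36), the homeobox gene En1 (5.13 ± 0.46), Sox11 (2.79 ± 0.27) and Meis1 (3.91 ± 0.47). Of 23 members of the primitive endoderm and endoderm list, 13 rose and 2 fell (13 and 2 adjusted over the list alone), led by genes of the extracellular matrix: the collagen chaperone Serpinh1 (4.01 ± 0.30), Col4a2 (3.0 ± 0.27), Col4a1 (2.53 ± 0.24) and Sparc (2.27 ± 0.27). In the same libraries 22 of 23 fibroblast feeder cells markers rose. Of 22 trophectoderm genes, 15 rose and 2 fell (15 and 2 adjusted over the list alone). The keratins Krt8 (11.03 ± 1.94 to 706 ± 347 CPM, 6.0 ± 0.52) and Krt18 (5.94 ± 0.45) and Gata3 (4.44 ± 0.44) rose, and Tfap2c fell (-2.55 ± 0.25). By camera, the adjusted p was 1.35e-06 for mesoderm and primitive streak, 0.000562 for neuroectoderm, 0.00227 for primitive endoderm and endoderm and 0.000939 for trophectoderm. In the same order these lists had adjusted p = 0.218, 0.218, 0.33 and 0.378 with an estimated correlation. Within the first number series 16, 9, 11 and 10 members of these lists rose and within the second 15, 8, 12 and 10. Without shControl replicate 2, 9 members of the trophectoderm list rose.

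Of 21 members of the formative and primed epiblast list, 10 rose and 5 fell in shTrim28 (11 and 5 adjusted over the list alone). Cdh2 went from 3.04 ± 1.17 to 112 ± 38.8 CPM (5.19 ± 0.41, adjusted p = 1.91e-06), and Pou3f1 (3.01 ± 0.27), Sox4 (2.14 ± 0.27) and Fgf5 (3.78 ± 0.60) rose. Of 49 bivalent developmental regulators, 34 rose and 2 fell (35 and 2 adjusted over the list alone). Wt1 (4.14 ± 0.36), Tbx20 and the homeobox gene Pitx2 (5.44 ± 0.53) rose, and Sfrp1 fell (-2.12 ± 0.27). Of 28 genes of the Hox clusters, 18 rose and 0 fell (18 adjusted over the list alone), from low levels. Hoxd8 rose by 4.95 ± 0.64 and Hoxb8 by 3.36 ± 0.56. Hoxd9 had 563 counts against 1 (CPM ratio 315, 95% counting interval 56.4 to 12500) and Hoxb1 646 against 1 (CPM ratio 362, interval 64.7 to 14300). The camera adjusted p was 0.0403 for formative and primed epiblast, 1.97e-08 for bivalent developmental regulators and 1.07e-05 for Hox clusters. In the same order these lists had adjusted p = 0.391, 0.256 and 0.323 with an estimated correlation. Within the first number series 11, 27 and 11 members of these lists rose, and within the second 7, 24 and 9. The formative and primed epiblast list was no longer called without shControl replicate 1, shTrim28 replicate 1 or shTrim28 replicate 4 (formative and primed epiblast list in Trim28 knockdown, adjusted p = 0.259, 0.0514 and 0.119). Without shControl replicate 2, 8 members of the Hox clusters list rose and 0 of the formative and primed epiblast list fell. Of that last list 3 members fell without shTrim28 replicate 1, and 2 without replicate 2 or without replicate 3.

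In shTrim28 the 2-cell stage and imprinted lists held more rises than falls, and the PRC2, Trim28 complex and germline lists more falls than rises. Of 30 members of the 2-cell stage list, 27 rose and 0 fell (28 up and 1 down adjusted over the list alone), with a median of 3.25. Usp17lc went from 2.29 ± 0.979 to 30.8 ± 8.49 CPM (3.76 ± 0.35, adjusted p = 4.87e-06), and Gm4340 (3.91 ± 0.40), Tdpoz3 (5.26 ± 0.55) and Tmem92 (3.26 ± 0.34) rose; apart from Tmem92 these are multi-copy genes. Of 47 imprinted genes, 24 rose and 5 fell (24 and 5 adjusted over the list alone). Peg10 (210 ± 149 to 2618 ± 1050 CPM, 3.64 ± 0.44), Ndn (3.07 ± 0.29) and the growth factor Igf2 (6.84 ± 0.80), all paternally expressed, rose, and the maternally expressed Slc22a18 fell (-3.09 ± 0.37). Of 13 PRC2 subunits, 1 rose and 8 fell (1 and 8 adjusted over the list alone). Eed (chromosome 7, 89954654 to 89980983; 253 ± 34.2 to 115 ± 25.4 CPM, -1.14 ± 0.17, adjusted p = 0.000156), Suz12 (-0.97 ± 0.15), Mtf2 (-1.30 ± 0.21), Ezh1 (-1.14 ± 0.19) and Ezh2 (-0.61 ± 0.14) fell. Of 25 members of the Trim28 repressor complex list, 2 rose and 7 fell (2 and 7 adjusted over the list alone). Zfp57, a zinc finger protein of imprinting control regions, fell by 1.66 ± 0.21 on the log2 scale, the HUSH subunit Fam208a by 0.82 ± 0.16 and Morc3 by 0.76 ± 0.15, and Pphln1 rose (1.24 ± 0.20). Setdb1 did not pass (-0.20 ± 0.13, adjusted p = 0.256). Of 38 germline genes, 6 rose and 14 fell (6 and 15 adjusted over the list alone), with Smc1b (-2.87 ± 0.35), Dazl (-1.97 ± 0.30), Stra8 and Hormad1 (-2.87 ± 0.45) among the latter. The camera adjusted p was 7.54e-12 for the 2-cell stage list, 0.000576 for imprinted, 0.00334 for PRC2 subunits and 0.017 for germline. In the same order these lists had adjusted p = 0.288, 0.288, 0.218 and 0.391 with an estimated correlation, and the Trim28 repressor complex list was not called (adjusted p = 0.0593). Within the first and the second number series, 22 and 27 members of the 2-cell stage list and 22 and 15 of the imprinted list rose, while 7 and 6 PRC2 subunits, 6 and 1 members of the Trim28 repressor complex list and 14 and 8 of the germline list fell. Without shControl replicate 1, 9 members of the germline list fell and the list was no longer called (germline list in Trim28 knockdown, adjusted p = 0.203). Without shControl replicate 2, 3 members of the germline list rose and 3 of the imprinted list fell.

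More cell cycle genes fell than rose in shTrim28, and more interferon genes rose than fell. Of 30 DNA replication genes, 2 rose and 18 fell (2 and 18 adjusted over the list alone), among them the polymerase gene Pola1 (-1.23 ± 0.17, adjusted p = 8.19e-05), Mcm6 (-0.72 ± 0.14), Orc1 (-0.79 ± 0.16) and Rfc4 (-0.81 ± 0.16). Of 32 genes of G2 and mitosis, 0 rose and 16 fell (16 adjusted over the list alone), among them Hmmr (-0.94 ± 0.18), the kinesin Kif23 (-0.66 ± 0.13), Fbxo5 (-0.87 ± 0.18) and the checkpoint kinase Bub1b (-0.70 ± 0.14). Of 30 p53 targets, 12 rose and 3 fell (13 and 3 adjusted over the list alone). Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21 (50.9 ± 9.84 to 174 ± 44.6 CPM, 1.78 ± 0.22), Pmaip1 (1.93 ± 0.25) and Ddit4l (1.71 ± 0.20) rose, and Gdf15 fell (-3.57 ± 0.41). Of 28 interferon response genes, 18 rose and 5 fell (19 and 5 adjusted over the list alone). Oasl2 (6.62 ± 0.55) and the chemokine Cxcl10 (5.77 ± 0.58) rose, Isg15 had 1204 counts against 1 (CPM ratio 674, 95% counting interval 121 to 26700), and Oas3 fell (-2.34 ± 0.26). The camera adjusted p was 0.000153 for DNA replication, 5.08e-05 for G2 and mitosis, 0.0274 for p53 targets and 0.000939 for interferon response. In the same order these lists had adjusted p = 0.332, 0.288, 0.391 and 0.362 with an estimated correlation. Within the first and the second number series, 10 and 4 members of the DNA replication list and 8 and 3 of the G2 and mitosis list fell, and 11 and 11 p53 targets and 18 and 11 interferon response genes rose. Without shControl replicate 2, 10 members of the DNA replication list and 10 of the G2 and mitosis list fell, 3 of the interferon response list fell, and the p53 targets list was no longer called (p53 targets list in Trim28 knockdown, adjusted p = 0.0617). In the G2 and mitosis list 7 members fell without shControl replicate 1 and 10 without shTrim28 replicate 3.

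Of 24 genes of the integrated stress response, 5 rose and 12 fell in shTrim28 (5 and 13 adjusted over the list alone). Atf3 (3.64 ± 0.43) and Cebpb (2.07 ± 0.28) rose, and Gdf15 and the tRNA synthetase gene Cars (-1.19 ± 0.18) fell. Of 30 members of the hypoxia and glycolysis list, 2 rose and 12 fell (2 and 12 adjusted over the list alone), with Vegfa (-2.08 ± 0.24), phosphofructokinase Pfkp (826 ± 90.8 to 155 ± 74.1 CPM, -2.42 ± 0.28) and Bnip3 (-2.0 ± 0.30) down and P4ha2 up (1.18 ± 0.19). Of 23 members of the cholesterol synthesis list, 10 rose and 0 fell (10 adjusted over the list alone), with Sc5d (1.17 ± 0.21), Pcsk9 (1.33 ± 0.32), Idi1 (0.72 ± 0.19) and Hsd17b7 (0.88 ± 0.23). Of 6 topoisomerases, Top2a, the mitochondrial Top1mt (-0.78 ± 0.21) and Top3b (-0.42 ± 0.14) fell and Top2b rose (0.72 ± 0.26, adjusted p = 0.0403), with 1 up and 3 down adjusted over the list alone. The camera adjusted p was 0.0316 for the integrated stress response (adjusted p = 0.391 with an estimated correlation) and 0.00294 for hypoxia and glycolysis (adjusted p = 0.391 with an estimated correlation). The cholesterol synthesis (adjusted p = 0.0999) and topoisomerases (adjusted p = 0.242) lists were not called. Within the first and the second number series, 12 and 6 members of the integrated stress response list, 8 and 7 of the hypoxia and glycolysis list and 2 and 0 topoisomerases fell, and 2 and 3 members of the cholesterol synthesis list rose. Without shControl replicate 1, 3 members of the integrated stress response list and 4 of the cholesterol synthesis list rose and 0 topoisomerases fell. Without shControl replicate 2, 6 members each of the integrated stress response and hypoxia and glycolysis lists fell, 2 of the cholesterol synthesis list rose, and the integrated stress response list was no longer called (integrated stress response list in Trim28 knockdown, adjusted p = 0.0857), nor was it without shTrim28 replicate 1 (adjusted p = 0.0553). Without shControl replicate 2, Pcsk9 in Trim28 knockdown (1.13, adjusted p = 0.0712) and Hsd17b7 in Trim28 knockdown (0.53, adjusted p = 0.163) lost their calls. Idi1 in Trim28 knockdown lost its call without either shControl library (adjusted p = 0.0522 and 0.0668) and Top1mt in Trim28 knockdown without shControl replicate 1 (adjusted p = 0.0602). Top3b in Trim28 knockdown lost its call when any 1 of 5 libraries of the shRNA comparison was left out (adjusted p = 0.0586 to 0.118), and Top2b in Trim28 knockdown when any 1 of 7 of the 12 libraries was (adjusted p = 0.0504 to 0.258).

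**Figure D3:**
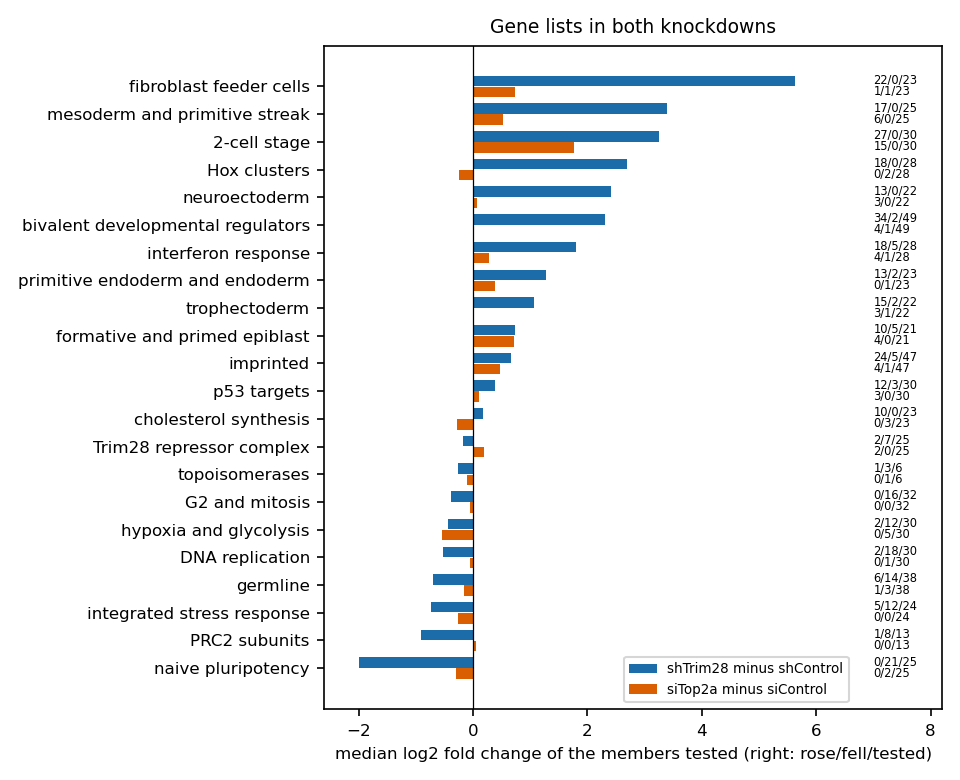
Median log2 fold change of the members tested of each of the 22 gene lists in shTrim28 minus shControl (blue) and siTop2a minus siControl (orange), with the numbers that rose, fell and were tested at the right. In shTrim28 the medians run from -1.99 for naive pluripotency to 5.63 for fibroblast feeder cells, which is 3.80 with members at 0 counts in shControl set to their lower bound.

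Genes that changed in both knockdowns mostly moved in the same direction. Of the 461 genes that rose in siTop2a, 322 also rose in shTrim28, where 107 would be expected for independent lists, and of the 373 that fell, 231 also fell, where 65.5 would be expected (one-sided Fisher's exact test, p = 1.19e-102 and p = 5.99e-83). The genes that rose in both by the largest smaller change were, by fitted values, Isg15, the AMPA receptor regulator Shisa6, protocadherin Pcdh17, troponin Tnnt3 and Synpo2l. The place of Isg15, with 0 counts in siControl and a level at least 8.07-fold higher, rests on the prior count: at that bound it would fall below the other 4. With few counts in siControl, the siTop2a CPM ratios were 34.6 for Shisa6 (95% counting interval 9.42 to 288), 34.2 for Pcdh17 (5.95 to 1370) and 16.9 for Tnnt3 (5.63 to 82.9), and Synpo2l went from 0.0817 ± 0.00516 to 1.32 ± 0.718 CPM. Vstm2l, Unc5a, Grin2c, Hal and Nxph4 fell most in both, by 2.70, 2.63, 2.60, 4.15 and 3.10 on the log2 scale in shTrim28. Opposite changes were called for 6 genes up in siTop2a and down in shTrim28, where 81.0 would be expected, and for 17 down in siTop2a and up in shTrim28, where 86.6 would be expected. The 5 largest of these were Gata2 (-1.31 in siTop2a and 2.25 in shTrim28), Tspan18 (-1.26 and 2.05), Sema4c (-1.23 and 2.34), Man1c1 (-1.13 and 1.28) and Fam114a1 (-1.28 and 1.03). Man1c1 in Trim28 knockdown (1.21, adjusted p = 0.0556) and Fam114a1 in Trim28 knockdown (0.71, adjusted p = 0.258) lost their calls without shControl replicate 2, Fam114a1 also without shTrim28 replicate 1 or 2 (adjusted p = 0.0677 and 0.0503), and all 5 siTop2a calls were lost without either siControl library (adjusted p = 0.168 for Gata2 in Top2a knockdown to 0.456 for Sema4c in Top2a knockdown). Across genes, which are not independent replicates, the log2 fold changes of the knockdowns had a Pearson r of 0.505 and a Spearman rho of 0.387. No library entered the group means of both comparisons. The spread of each gene, however, was estimated over all 12 libraries, so genes of low spread can be called in both. The numbers expected for independent lists and the Fisher p-values are therefore a description only. The number of genes changed in the same direction in both knockdowns was 553, and 125 with the siRNA libraries numbered 4 to 9, 1105 with siTop2a replicates 3 and 4 only, 1141 with DESeq2, 227 with the series as a term, 7 without siControl replicate 1, 3 without siControl replicate 2, 171 without siTop2a replicate 3 and 353 without siTop2a replicate 4.

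**Figure D4:**
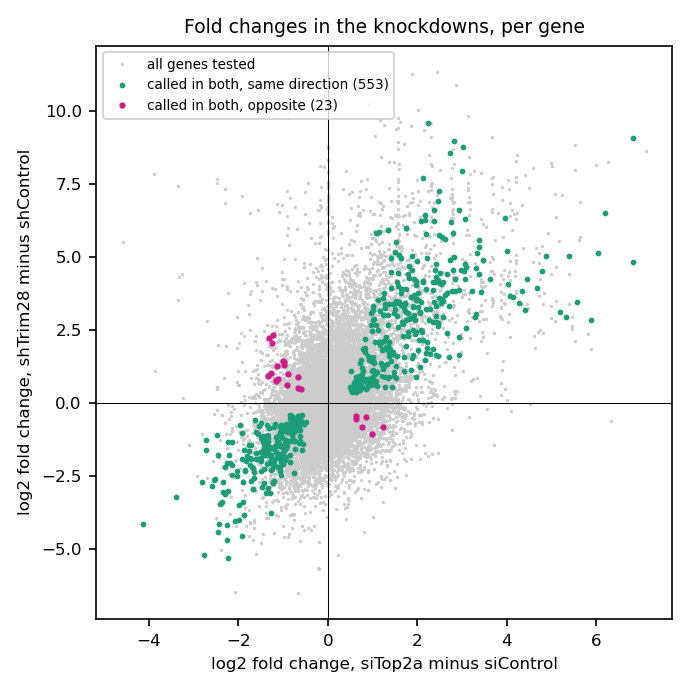
Log2 fold change of each gene tested in shTrim28 minus shControl (vertical) against siTop2a minus siControl (horizontal). The 553 genes called in both in the same direction are green and the 23 called in opposite directions are pink; genes with few or 0 control counts have fitted values that depend on the prior count.

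The difference between the responses was tested directly, as the Top2a effect minus the Trim28 effect. The knockdown target, the mode of delivery (siRNA or shRNA) and the depth of the knockdown, smaller for Top2a RNA than for Trim28 RNA, are confounded in it. It differed from 0 for 3098 genes, 1114 higher and 1984 lower in the Top2a knockdown. The naive pluripotency list had 16 of 25 members higher in the Top2a knockdown (22 adjusted over the list alone), among them Sox2 (1.60, adjusted p = 0.0128) and Nanog (1.38, adjusted p = 0.0204), and Pou5f1 did not pass (1.05, adjusted p = 0.0549). Of 13 PRC2 subunits, 7 were higher and 1 lower (8 and 1 adjusted over the list alone), with Suz12 (1.30, adjusted p = 0.00212), Eed (1.2, adjusted p = 0.00713) and Mtf2 (1.26, adjusted p = 0.0138) higher and Ezh2 without a call (0.22, adjusted p = 0.508). Of the 23 fibroblast feeder cells markers, 13 were lower (13 adjusted over the list alone), among them Col1a1 (-6.19, adjusted p = 1.09e-05). Bivalent developmental regulators had 17 of 49 lower (22 adjusted over the list alone), Hox clusters 7 of 28 lower (12 adjusted over the list alone) and the 2-cell stage list 5 of 30 lower (5 adjusted over the list alone). The keratins Krt42 (3.89) and Krt17 (3.57), the protease gene Napsa (3.88), Piwil4 (3.88) and Angptl8 (3.68) were the most positive of the named differences, and Acta2 (-8.01) and Cxcl11 (-8.00) were among the most negative, with Robo2, Ly6c1 and Slc5a7, whose shControl libraries held 1, 0 and 0 counts. In camera 16 of the 22 lists differed, the naive pluripotency (adjusted p = 1.53e-08) and fibroblast feeder cells (adjusted p = 3.80e-15) lists among them, and 0 of the 22 with an estimated correlation, where the lowest was adjusted p = 0.125. The number of genes whose response differs between the knockdowns was 1209 without siControl replicate 1, 1029 without siControl replicate 2, 2022 without shControl replicate 1 and 1335 without shControl replicate 2, and 2969 with the siRNA libraries numbered 4 to 9.

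The control groups, shControl against siControl, differed in 0 of 19756 genes in edgeR's test, with 1669 at an unadjusted p under 0.05 and 41 called by DESeq2. Without a filter on low counts 162 genes passed. At the preset correlation camera called 4 lists: 2-cell stage (median 0.995, adjusted p = 1.68e-07) and Trim28 repressor complex (adjusted p = 0.00249) higher in shControl, and hypoxia and glycolysis (median -0.42, adjusted p = 3.34e-06) and primitive endoderm and endoderm (adjusted p = 0.019) lower. None was called with an estimated correlation (lowest adjusted p = 0.861). On simulated counts without a number series or chromosome shifts, this design of 2 libraries against 2 recovered 22% of genes changed by 1 on the log2 scale. It recovered 80% of those changed by 2. Of the 2-cell stage genes, Usp17lc measured 1.30 ± 0.0247 CPM in siControl and 2.29 ± 0.979 CPM in shControl, and Tmem92 3.17 ± 0.319 and 4.19 ± 0.900 CPM.

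The genes of chromosomes 1 and 11 were shifted together in some libraries, controls included. Against the mean of the 4 control libraries, the median log2 level of chromosome 1 genes was 0.27 in shControl replicate 1, 0.32 in shTrim28 replicate 1 and 0.26 in shTrim28 replicate 2, all of the first number series. It was -0.11 in shControl replicate 2 and -0.01 and -0.13 in shTrim28 replicates 3 and 4, all of the second. It was -0.35, -0.36, -0.31 and -0.28 in siTop2a replicates 1 to 4, which span both series. In siControl replicates 1 and 2 it was -0.13 and -0.01. For chromosome 11, which carries Top2a itself, the medians were 0.46, 0.47, 0.26 and 0.14 in siTop2a replicates 1 to 4. In siControl replicates 1 and 2 they were 0.06 and 0.1, so siTop2a replicate 4 lay little above its own controls. Between groups, siTop2a minus siControl, the median was -0.27 for chromosome 1 and 0.25 for chromosome 11. Chromosome 11 held 7.7% of the genes tested and 94 of the 461 genes that rose in siTop2a (20.4%), Gabra1, Irgm1, Grm6, Tmem92, Wnt3, Meis1, Hand1, Morc2a and Shisa6 among them, with 18 of the 373 that fell. Some rose by far more than the chromosome median of 0.25, such as Irgm1 (3.39) and Wnt3 (2.18). These 2 genes also rose in shTrim28 (5.6 and 6.46), where the chromosome 11 median was -0.06. What part of the smaller rises follows the chromosome was not tested. Chromosome 1 held 6.1% of the genes tested, 21 of those that rose and 37 of those that fell (9.9%), Mael, Cxcr4, Mcm6 and Sema4c among them. Outside chromosome 11, 367 genes rose and 355 fell. In shTrim28 minus shControl the chromosome 1 median was 0.01 and that of chromosome 17 was -0.16. In siTop2a replicates 1 and 2 minus replicates 3 and 4, the medians were 0.3 for chromosome 11, 0.22 for chromosome 6, 0.2 for chromosome 8 and 0.19 for chromosome 7. After a fit on GC content, length and expression level of the genes they were 0.19, 0.29, 0.12 and 0.08 in the same order. Whether chromosomes 6, 8 and 17 moved as a whole was not tested. The medians of 11 mitochondrial genes were 0.73 and 0.52 in siTop2a replicates 3 and 4, against -0.01 and 0.07 in replicates 1 and 2. Those of 5 Y chromosome genes were 0.58 and 0.48, against -0.18 and -0.34.

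**Figure D5:**
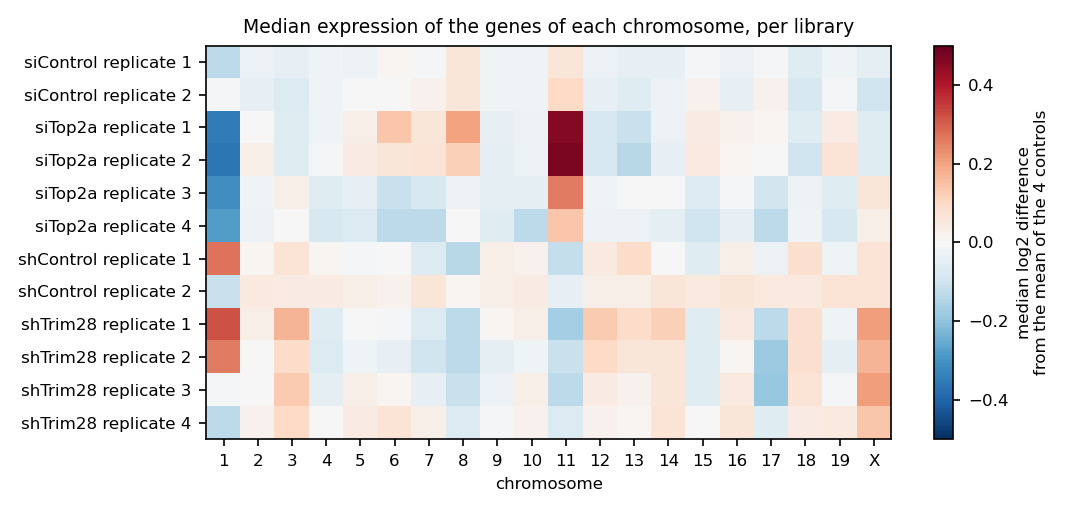
Median log2 difference of the genes of each chromosome from the mean of the 4 control libraries, per library, as a colour from -0.5 (blue) to 0.5 (red). Chromosome 1 is at 0.27 in shControl replicate 1 and between -0.36 and -0.28 in siTop2a, and chromosome 11 at 0.46 and 0.47 in siTop2a replicates 1 and 2.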

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

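The tests of added reads in genes more than halved and of a deeper Top2a loss in siTop2a, of feeder cell RNA, of a single hairpin, of chromosome copies and of the knockdowns as a source of the chromosome shifts were chosen after the results were seen. In groups of 4 libraries, 15 of 295 sets of values held a library far from the other 3, which is 5.1% against about 5% by chance. In each, the ratio of that library's gap to the group's range exceeded Dixon's 95% critical value. In siTop2a it was 0.888 for Ezh2 (204 CPM in replicate 1, 176 to 179 in the others), 0.855 for Krt8, 0.882 for Lcor, 0.893 for Piwil4, 0.984 for Acta2 (4.22 CPM in replicate 3, 1.32 to 1.37 in the others) and 0.832 for Shisa6. In shTrim28 it was 0.868 for Igsf21, 0.917 for Plk3, 0.842 for Peg10 (4182 CPM in replicate 3, 1932 to 2287 in the others), 0.861 for Ezh1, 0.929 for Top1mt, 0.912 for Sc5d, 0.910 for Vstm2l, 0.862 for Nxph4 and 0.846 for the share of reads in no feature (7.25% in replicate 3).

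The effects of the knockdowns differed for 3098 genes in the direct test. Among the named genes the Top2a effect minus the Trim28 effect was 3.89 for Krt42, 3.88 for Napsa, 3.88 for Piwil4, 3.68 for Angptl8, 3.57 for Krt17, -9.33 for Robo2, -8.53 for Ly6c1, -8.27 for Slc5a7, -8.01 for Acta2 and -8.00 for Cxcl11. The fitted values of Robo2, Ly6c1, Slc5a7 and Cxcl11 depend on the prior count, since shControl held 1, 0, 0 and 2 counts of them. Outside the gene counts, the share of unmapped reads was 3.06% on average in shTrim28 and above both shControl libraries (1.93% and 1.99%) in each, and that of multimapping reads was 5.74% on average against 5.36% and 5.36%. Unmapped reads made up 4.63% and 4.61% in siTop2a replicates 1 and 2 and 2.02% and 2.31% in replicates 3 and 4, against 4.55% and 4.08% in siControl. What these reads hold was not tested.

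Hairpins sh4 and sh1 differed in 2357 genes with the number series as a term (1134 higher and 1223 lower with sh4) and in 584 without it, and siTop2a replicates 3 and 4 differed from replicates 1 and 2 in 2605 genes (1159 higher, 1446 lower). A shift shared by the libraries of the second number series is argued against by its correlation across 14558 genes, which was -0.126 with the series difference in shTrim28 and -0.159 with that in shControl, while those 2 differences correlated with each other at 0.511. Added reads from introns or intergenic sequence are argued against only for the 174 genes lower in replicates 3 and 4 by 1 on the log2 scale by more than 2 SE, since added reads lower a gene through scaling alone and at most 12.3% of reads lay in no exon. For the other genes they stay open: that 55.5% of the genes that differed were lower decides nothing, because scaling to a common total lowers some genes when others rise, and replicates 3 and 4 had more reads in no exon (9.16% and 12.3% against 4.76% and 4.73%). A deeper loss of Top2a in one pair (1.24 times the Top2a CPM in replicates 3 and 4) cannot be told apart from a batch of these siRNA libraries alone. The reagent of replicate 1 is argued against as the source of this split, since replicate 2 carries the label si12 of replicates 3 and 4. The chi-square per degree of freedom of siTop2a replicate 2 was 4.62 against replicate 1 and 62.1 and 72.7 against replicates 3 and 4.

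Markers of fibroblasts rose in shTrim28 (22 of 23), and R1/E cells may be grown on fibroblast feeder cells, although the labels do not mention feeders. An effect of a single hairpin is argued against, since 21 members rose with sh1 alone and 19 with sh4 alone. RNA from one source of feeder cells would keep its genes in a fixed ratio, and the spread of the members around their common level was 1.23 times that of random sets of risen genes of like expression, wider than 93.5% of 1000 such sets, which does not decide. Col1a1 averaged 3.4 CPM in shControl and 5.94 in siControl against 352 in shTrim28, and Col3a1 0.284 and 0.039 against 56.4. Mmp2 averaged 20.7 and 37.6 against 64.3. Feeder RNA as the source of these collagens would thus have to reach the shTrim28 libraries and hardly the controls. The ratio of Postn to Col1a1 varied 18-fold between shTrim28 libraries and that of Col3a1 to Col1a1 3.81-fold, so RNA of feeder cells in varying mixtures and a change of cell state after the knockdown both stay open.

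Genes of chromosomes 1 and 11 were shifted together in some libraries, and differing copies of whole chromosomes are a candidate explanation, as a hypothesis found on the same data. In the differences tested for whole chromosomes, every 25 Mb bin with at least 20 genes moved the same way: the lowest bin median was 0.28 on chromosome 1 (8 bins, shControl replicate 1 minus replicate 2) and 0.32 on chromosome 11 (5 bins, siTop2a replicates 1 and 2 minus siControl), whereas in siTop2a replicates 3 and 4 the chromosome 11 bins ran from 0.04 to 0.29, which leaves a whole-chromosome shift there open. GC content, length and expression level of the genes are argued against as the whole source, since 82% and 87% of these shifts were left after fitting them. The knockdowns are argued against for chromosome 1 in shControl, whose libraries differed by 0.38. Over the shRNA libraries this shift followed the number series (0.26 to 0.32 in the first, -0.13 to -0.01 in the second). The siControl libraries, also of the first series, were at -0.13 and -0.01, which argues against a rise shared by that whole series. A difference between the series within the shRNA libraries stays open. The shifts in siTop2a were not separated from the knockdown. DNA copy number was not measured, and genes of chromosome 11 make up 94 of the 461 rises in siTop2a.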

How the results depend on the processing

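The fits with siTop2a replicates 3 and 4 only and with the 4 siRNA libraries numbered 4 to 9 alone were chosen after the data were seen. The number of genes changed by Top2a knockdown, 834, stayed within 1.5 times under other scalings, a CPM filter and a strand column (654 to 1000). It was 1968 with DESeq2, 1841 with no filter on low counts, 309 with the library series term, 175 with siRNA libraries numbered 4 to 9, 2353 with only siTop2a replicates 3 and 4, 1395 with only the 6 siRNA libraries, 7049 with the 4 siRNA libraries numbered 4 to 9 fitted alone, 545 with a log2 change of at least 1, 53 at an adjusted p under 0.01, and 3 to 1285 with 1 library left out. The series term fitted 1 shift common to siRNA and shRNA libraries. Across genes, however, the siTop2a difference correlated at -0.126 with the series difference in shTrim28 and at -0.159 with that in shControl. The counts with this term are therefore not freed of the siTop2a difference. The labels hold replicate numbers but no statement of pairing. With the replicate number as a block the counts were 2045 for Top2a, 9479 for Trim28 and 5757 for the difference. In that fit replicates 3 and 4 of each knockdown had no control library of the same number, so the block counts rest on replicates 1 and 2. The block also joined shTrim28 replicate 2 of the first number series with shControl replicate 2 of the second. The number of genes changed by Trim28 knockdown, 8055, was 3982 with shRNA libraries numbered 64 to 66, 5288 with a log2 change of at least 1 and 5310 at an adjusted p under 0.01; the other alternatives gave 5403 to 9479 and leaving out 1 library 5408 to 8630. For genes whose response differs between the knockdowns, the count of 3098 became 1063 at an adjusted p under 0.01 and 1029 to 4541 with 1 library left out.

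For genes changed in the same direction in both knockdowns, the count of 553 became 1141 with DESeq2, 1132 with no filter on low counts, 890 with the replicate block, 227 with the library series term, 125 with siRNA libraries numbered 4 to 9, 1105 with only siTop2a replicates 3 and 4, 36 at an adjusted p under 0.01 and 3 to 779 with 1 library left out. For genes that differ between the control groups, the count of 0 in edgeR, with 1669 at an unadjusted p under 0.05, became 41 with DESeq2 and 162 with no filter on low counts. Stricter thresholds keep fewer genes by construction; the cause of the other moves was not tested. Of 308 list tests per knockdown under an alternative, 292 in Top2a and 280 in Trim28 kept the camera direction and side of the threshold, 8 and 26 lost the call, 8 and 2 gained it and 0 reversed. The settings were library size alone, the estimated correlation and each of the 12 libraries left out, those of the other delivery included. Camera called 6 of the 22 lists in Top2a and 19 in Trim28, and with the estimated correlation 0 in either. Lists and named genes uncalled under both settings count as kept, so the kept shares do not show how stable the calls are. Of 4196 tests of named genes in Top2a 3554 kept their side of the threshold, 471 lost and 170 gained the call; of 4396 in Trim28 4262 kept it, 122 lost and 11 gained the call. Among those that kept it, 54 and 20 values uncalled under both settings changed sign. Hmmr in Top2a knockdown reversed to -0.24 with the 4 siRNA libraries numbered 4 to 9 fitted alone, and Ddx58 in Trim28 knockdown to 0.92 with only shRNA libraries numbered 1 to 3; the cause was not tested.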

Other observations

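All values here come from groupings chosen after the data were seen. Of 22 gene families taken by name, 11 held more rises and 1 more falls in shTrim28 than chance in Fisher's exact test at an adjusted p under 0.05. All 15 guanylate-binding proteins and immunity-related GTPases tested rose (median 4.27 with the 4 members at 0 counts in shControl set to their lower bound, adjusted p = 2.64e-08), as did 17 of 20 genes of the protocadherin gamma cluster (adjusted p = 3.85e-07), 24 of 41 collagen genes, with 6 down (adjusted p = 2.72e-05), 22 of 36 olfactory receptor genes, with 3 down (adjusted p = 2.72e-05), and 12 of 17 Wnt genes (adjusted p = 0.000661). Rhox genes had 0 of 10 up and 6 down (adjusted p = 0.0218). In siTop2a, 5 of the 15 guanylate-binding proteins and immunity-related GTPases rose (adjusted p = 0.000295), and no other family passed. With camera at an estimated correlation the lowest adjusted p over the families was 0.125 in shTrim28 and 0.66 in siTop2a. The filter kept genes expressed in a single group, so members silent elsewhere entered only through shTrim28. Olfr1331, for instance, averaged 0 CPM in siControl, siTop2a and shControl and 0.487 in shTrim28. The rise of such members was set by the filter. The shares and Fisher p-values of families that hold them are a description only. Many members of these families share reads between copies.

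In shTrim28 the median log2 fold change of the 650 protein-coding genes longer than 200 kb was 0.36, with 0.36 and 0.38 within the first and the second number series. For those under 5 kb it was 0.05, with 0.13 and -0.01 within these series. In siTop2a the median for genes under 5 kb was 0.15 in replicates 1 and 2 and -0.16 in replicates 3 and 4. Between hairpins, with the number series as a term, Trim28 was higher with sh4 by 1.21 on the log2 scale, and 18 of 25 naive pluripotency genes were higher with sh4 (median 0.90). In siTop2a replicates 3 and 4, 10 of 30 genes of the 2-cell stage list were higher than in replicates 1 and 2, as were 9 of 32 genes of G2 and mitosis, and 8 of 30 DNA replication genes were lower. The other lists had at most 7 members higher and 5 lower. Of 1531 pseudogenes tested, 86 were higher and 235 lower there, among them 138 of the 174 genes lower by 1 on the log2 scale by more than 2 SE. For the siTop2a pairs, a shift shared by the second number series, added reads and a deeper loss of Top2a were tested as described above. No other explanation of these values was tested.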
